A study of Homo sapiens with 8 samples.

How the data were processed

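Per the labels' protocols, HAP1 cells and their null derivatives were grown to 70% confluence, RNA was taken with Trizol, and libraries were made with a stranded mRNA kit and 4 barcoded adapters. Per the submitters' processing notes, STAR, Partek 4.0 and the hg19 build were used. The test, the normalization and the gene annotation are not given in the sources used here.

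The 2 tables used hold the authors' own comparisons of each null group with wildtype. Each gives, per the file headers, the total reads of a gene over all samples (an estimated count, whole within 0.001 for 39.1% of the 19541 symbols, summing to 631 M reads), a p-value, an adjusted p-value (FDR), a ratio of the null group to wildtype and a signed fold, all made by the authors. The authors' signed fold, a score in sign, equals the ratio where that is 1 or more and minus its inverse otherwise. Where no table is singled out, the authors' deposited table is the full one. The adjusted p-value equals the Benjamini-Hochberg adjustment of the authors' p-value. Of the symbols, 27 had been turned into dates and 4 were repeated.

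Because the tables hold comparisons, no test was run on the full table. Genes at an authors' FDR under 0.05 were counted. Gene lists were fixed before the data were examined, as were the groups, the thresholds and the rule for named genes, but reading that rule's condition on samples, and all of it between nulls, from recovered reads was decided later. For each list with at least 5 measured members, calls were counted, also adjusted over the list alone, and the median log2 ratio was placed among 10000 random lists matched on total reads in 50 bins. On simulated lists of 25 genes, 97% of those shifted by 1 on the log2 scale came out above percentile 97.5, but only 55% of those shifted by 0.5, and 2.5% of unshifted lists. The simulated genes were independent, so these shares do not hold for lists whose members vary together. Mitochondrial transcripts were not analysed here. The named genes are the targets and SMARCA2, the 12 largest rises and 12 largest falls among calls with at least 50 reads in the higher group and, where reads per library were recovered, both null libraries on the same side of both wildtype libraries. For comparisons between nulls the 6 largest in each direction were taken, and for each list up to 4 members. A group without reads was given 3 reads over the group, and the fold is then a lower bound that covers counting error only. The other group entered with its recovered mean or, without recovered reads, with the lowest level that the total and the ratios allow, that of all reads lying in the deeper library of each group.

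Reads per library were recovered from the authors' ratios, an alternative chosen after seeing the data. A ratio behaved as the quotient of group means of reads over depth, each with a small constant, so that genes with a single read showed what 1 read adds in each library. With these 8 steps, the 3 ratios and a whole total, whole reads were solved for 4360 of 5728 genes tried (89.4% of totals up to 600 and 45.6% of larger totals up to 10000). The relative tolerance was 3e-07 for smaller and 1e-09 for larger totals. The second was tightened after a looser one had let decoys through, and at these settings 0 of 500 and 0 of 100 decoys, with ratios shifted by a factor of 1e-04, gave a solution. On simulated counts all 2660 small and 100 large genes were solved correctly and none of 182 with fractional reads. The libraries of a group are known only as deeper and shallower, not by passage or guide. The authors' p-value was not used in the recovery, and both null libraries lay beyond both wildtype libraries in 100% of recovered genes with a SMARCB1-null p-value under 0.05 and in 11% of those above 0.5 in the authors' deposited table. Separation of the libraries is therefore no evidence for a call beyond the authors' p-value. Implied levels of other genes came from total reads and ratios, with a median error of 0.675% to 1.14% per group on recovered genes. The 95th percentile of that error was 4.23% in wildtype, 4.68% and 4.52% in the SMARCB1 and SMARCA4 nulls and 14.9% in the double null.

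Recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, robust, all 8 libraries, the authors' scaling) in R 4.3.3 on 2369 genes past filterByExpr, with Benjamini-Hochberg adjustment at 0.05. Recovered genes are mostly low in reads and do not stand for the transcriptome. On simulated SMARCB1-null data with 1896 genes tested, 4% of genes raised 2-fold and 54% of those raised 4-fold were called, with 5 false calls among 1714 unchanged genes. TMM scaling moved the median log2 change by -0.09, -0.11 and -0.30 in the SMARCB1, SMARCA4 and double nulls, and the share of higher calls from 61% to 53%, from 69.6% to 58.6% and from 79.8% to 58.2%. Other alternatives were DESeq2 1.42.0, voom with limma 3.58.1, other filters, fits of 4 libraries and each library left out. In the fits with fewer libraries the genes tested were held to those of the full fit, a choice made after counts with a recomputed filter had been seen. With a library left out the recomputed filter tested 2604 to 3216 genes. It called fewer genes in 52 of 56 counts and none by edgeR in 7, where 251 to 425 genes had an unadjusted p under 0.05 and, on all 8 libraries, DESeq2 called 126 to 217 and voom 53 to 68. Recovery and lists used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

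The reference annotation is of another build than hg19, so it was used only for chromosome assignment (96.4% of symbols matched) and no coordinates are given. Reads of overlapping or near-identical genes, such as HLA and histone genes, cannot be told apart here, since the authors' counting is not given in the sources used here.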

Results

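RNA was sequenced from HAP1, an established near-haploid human cell line, and from HAP1 lines made null for SMARCB1, for SMARCA4 or for both. SMARCB1 and SMARCA4 are subunits of the SWI/SNF (BAF) chromatin remodelling complexes, and SMARCA4 is 1 of their ATPases. The 8 samples formed 4 groups of 2. Wildtype was sampled at passages 9 and 12, and each single null at passage 12 with 2 different guides. Both double-null samples had guide 1 for SMARCB1 and guide 2 for SMARCA4, each also the guide of 1 single-null sample. The double null was sampled at passages 15 and 18 of a single line. Separate cultures are not stated in the labels for the single nulls either, so p-values measure the spread between these samples. The spread within the wildtype and double-null groups is therefore that between passages of a line. The double null was also sampled at later passages than wildtype and both single nulls. Passage therefore cannot be told apart from loss of both genes against wildtype, or from loss of the second gene against a single null. Reads per library, recovered for 4360 genes, are given as depth-corrected reads, and for other genes an implied level per group was set from total reads and ratios. Relative depth, taken from what a single read added to the ratios of the authors' deposited table, put the libraries at 81.8 M and 68.3 M reads in wildtype, 70.2 M and 67.9 M in the SMARCB1 null, 92.3 M and 71.5 M in the SMARCA4 null and 103 M and 75.7 M in the double null.

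The targeted genes fell in the lines named for them. In the SMARCB1 null, SMARCB1 stood at a ratio of 0.109 to wildtype (FDR 1.79e-14) in the authors' deposited table, and in the double null at 0.182 (FDR 1.68e-13). SMARCA4 stood at 0.0918 in the SMARCA4 null (FDR 1.7e-79) and at 0.152 in the double null (FDR 5.56e-78) in the authors' deposited table. Each gene's ratio in the line null for the other gene was 0.97 for SMARCB1 (FDR 0.979) and 0.947 for SMARCA4 (FDR 0.639) in the authors' deposited table. SMARCA2, the alternative ATPase of the complex, had ratios of 0.734 in the SMARCB1 null, 1.05 in the SMARCA4 null and 1.05 in the double null in the authors' deposited table, none past the threshold (FDR 0.365, 0.972 and 0.899).

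In the SMARCB1 null, genes without wildtype reads rose and others fell to few or no reads. The neuropeptide gene VIP was at least 339.9-fold higher, and the desmosomal cadherins DSG1 and DSG4 were at least 319-fold and at least 188-fold higher (authors' FDR 0.0201, 1.25e-07 and 1.09e-05 in the authors' deposited table). Each of these bounds takes 3 reads over the wildtype pair as the floor and the lowest level that the total and the ratios allow, or the recovered mean where there is 1. MUM1L1 was at least 101-fold, the metalloprotease gene ADAMTS20 at least 85.4-fold and the heart and trophoblast transcription factor HAND1 at least 36.3-fold higher. ADAMTS20 had 138 and 131 depth-corrected reads in the 2 SMARCB1-null libraries, HAND1 had 82 and 32.5, and both had none in either wildtype library. CLEC1A, C6orf15, MYOC and CLEC4E, also without wildtype reads, were at least 72.9-fold, 62.8-fold, 55.9-fold and 50.2-fold higher. The phosphodiesterase PDE3A went from an implied level of 1.55 to 1707 depth-corrected reads per library (FDR 1.6e-48 in the authors' deposited table), and GIMAP4 from 0.957 to 1771 (FDR 6.4e-05 in the authors' deposited table).

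Among the falls, UNQ6494 had 115 and 122 depth-corrected reads in wildtype and none in the SMARCB1 null, at least 69.2-fold lower. MGAT4C went from 628 and 514 depth-corrected reads to none, at least 334-fold lower, a call made in the authors' deposited table (FDR 0.00577) and not with edgeR on recovered reads (adjusted p = 0.0842). OLIG3, a neural transcription factor, the protocadherin PCDHAC1 and TDGF1, a co-receptor of pluripotent cells, were at least 50.1-fold, 42.8-fold and 35.9-fold lower. CTCFL, the germline paralogue of CTCF, was at least 29.5-fold lower. HPGD, which breaks down prostaglandins, went from an implied level of 4518 to 6.26 depth-corrected reads per library, with a ratio of 0.00139 (FDR 4.64e-30) in the authors' deposited table. The ratio of the adhesion gene FLRT2 was 0.0055 (FDR 0.016) and that of CA8 was 0.00404 (FDR 0.043) in the authors' deposited table. MME, MS4A2 and CD200 went from implied levels of 2294, 1314 and 928 to 1.13, 1.75 and 1.84 depth-corrected reads per library.

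Genes of the cell cycle and targets of SRF were called lower more often than higher in the SMARCB1 null. Of 38 measured members of the cell-cycle list, 8 fell and 1 rose at an FDR under 0.05 in the authors' deposited table, or 10 and 1 when adjusted over the list alone. The cyclin CCND2 had a log2 change of -3.46 and the kinase CDK6 of -2.93, whereas CCND1 rose by 2.83 in the authors' deposited table. Of 24 cholesterol synthesis genes, 3 fell and 2 rose in the authors' deposited table (5 and 2 adjusted over the list alone). Of 36 HOX genes, 9 rose and 3 fell in the authors' deposited table (12 and 3 adjusted over the list alone), and HOXB8 rose by 3.71 on the log2 scale. Of 19 targets of the actin-sensing factor SRF, 8 fell and 3 rose in the authors' deposited table (9 and 4 adjusted over the list alone). ACTG2 and TGFB1I1 had log2 changes of -4.02 and -2.26 in the authors' deposited table, whereas ACTA2 rose by 3.82. Of 29 TGF-beta and BMP pathway genes, 7 rose and 2 fell in the authors' deposited table (9 and 4 adjusted over the list alone), with LTBP1 up by 4.29 and TGFB3 up by 2.00 on the log2 scale. In the SMARCA4 and double nulls 4 and 9 of these pathway genes rose and 2 and 3 fell in the authors' deposited table (5 and 9 rose and 2 and 5 fell adjusted over the list alone). In the SMARCB1 null, keratins KRT8 and KRT18 had log2 changes of -2.27 and -1.39, the 2 falls among 16 epithelial markers in the authors' deposited table (3 adjusted over the list alone). Among 20 imprinted genes 2 rose and 1 fell in the authors' deposited table (2 and 1 adjusted over the list alone), IGF2 by 7.87 and H19 by 1.38 on the log2 scale, and PEG10 by -0.95.

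Over all 19541 genes of the authors' deposited table, 2660 passed an FDR of 0.05 in the SMARCB1 null, 1535 higher and 1125 lower. Of these, 1146 changed at least 2-fold in the authors' deposited table. Among recovered genes, the deeper SMARCB1-null library held 39 that exceeded every other library over 4 times, skeletal muscle transcripts among them.

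**Figure D1:**
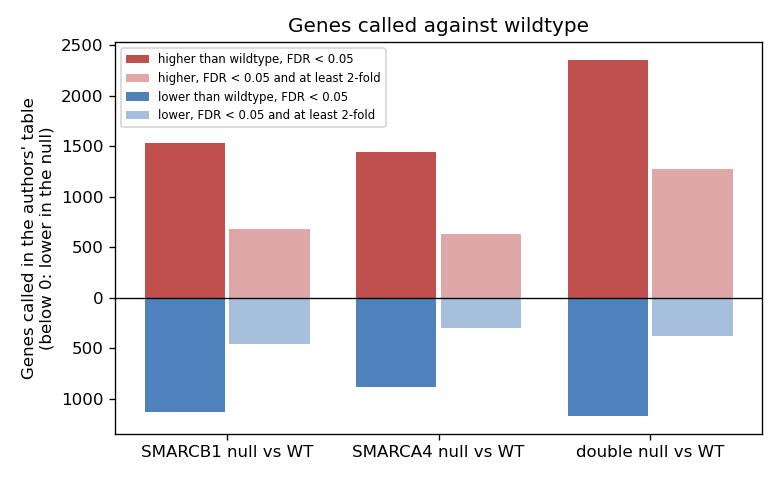
Genes called in each null group against wildtype in the authors' deposited table, drawn above 0 where higher and below 0 where lower than wildtype. Solid bars count genes at an FDR under 0.05 and pale bars those also changed at least 2-fold, and the double null had the most calls, 2350 higher and 1166 lower.

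Among the largest rises in the SMARCA4 null, the sodium channel SCN3A had a ratio of 1394 (FDR 0.0101), the glutamate transporter SLC17A8 of 693 (FDR 3.08e-30) and the membrane repair gene MYOF of 651 (FDR 0.00432) in the authors' deposited table. NLRP2 had a ratio of 450, the receptor PDGFRA of 133 and CYP26A1, which degrades retinoic acid, of 66.1 in the authors' deposited table (FDR 2.5e-13, 7.8e-12 and 2.76e-06). RGL3 and PRND, both without wildtype reads, were at least 166-fold and at least 39.1-fold higher. PRND had 64.9 and 58.4 depth-corrected reads in the 2 SMARCA4-null libraries. Ratios of PTPRH, the complement gene C3, SNCAIP and the interleukin receptor IL1R1 were 54.3, 49, 45.5 and 45 in the authors' deposited table.

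HPGD and MME fell here too, from implied levels of 4518 and 2294 to 1.53 and 1.72 depth-corrected reads per library (FDR 3.5e-37 and 0.0291 in the authors' deposited table). The homeobox gene TLX3 had 114 and 126 depth-corrected reads in wildtype and none in the SMARCA4 null, at least 83-fold lower, a call of the authors' deposited table (FDR 0.0415) that edgeR on recovered reads did not make (adjusted p = 0.267). Ratios of ARHGAP6, CSRNP3 and the hedgehog-binding gene HHIP were 0.0049 (FDR 6.62e-25), 0.00469 (FDR 2.4e-09) and 0.00828 (FDR 7.91e-15) in the authors' deposited table. ST18 and NAV3 had ratios of 0.00843 and 0.0103 in the authors' deposited table (FDR 0.0146 and 0.000471). The kinase SYK, the growth factor FGF5 and TMEFF2 went from implied levels of 317, 194 and 244 to 1.27, 0.883 and 0.962 depth-corrected reads per library. MGAT4C had 628 and 514 depth-corrected reads in wildtype and 2.56 and 2.2 in the SMARCA4 null, called in the authors' deposited table (FDR 0.0487) and not with edgeR on recovered reads (adjusted p = 0.102).

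Genes of hypoxia and glycolysis were called higher in the SMARCA4 null. Of 34 measured, 16 passed an FDR of 0.05 upward in the authors' deposited table (19, with 1 lower, adjusted over the list alone), led by ADM with a log2 change of 2.48, the lactate transporter SLC16A3 with 2.17 and the glucose transporter SLC2A3 with 1.64. Of 24 cholesterol synthesis genes, 9 rose in the authors' deposited table (12 adjusted over the list alone), INSIG1 by 0.99 and MVD by 0.84 on the log2 scale. Of 21 immediate-early and AP-1 genes, 10 rose in the authors' deposited table (12 adjusted over the list alone), with log2 changes of 3.36 for FOSL2, 3.24 for JUN, 3.01 for EGR3 and 2.41 for EGR1. Of 19 genes of MHC antigen presentation, 10 rose in the authors' deposited table (11 adjusted over the list alone), the regulator NLRC5 by 1.81 on the log2 scale and TAPBP to a ratio of 2.01. The medians of these lists lay at percentiles of 100, 99.98, 100 and 99.86 among 10000 random lists matched on total reads. Random lists do not allow for members that vary together, so these percentiles are a description and not a test. The double null, which also lacks SMARCA4, had 7 hypoxia and glycolysis genes lower and 3 higher in the authors' deposited table. There 4 cholesterol synthesis genes fell and 1 rose, whereas 9 immediate-early and AP-1 genes and 3 of MHC antigen presentation rose and 0 fell. In the SMARCB1 null 4 MHC genes rose and 0 fell in the authors' deposited table (7 and 0 adjusted over the list alone). The median log2 change of the MHC list was alike in the SMARCB1, SMARCA4 and double nulls, at 0.55, 0.52 and 0.56 (percentiles 99.93, 99.86 and 97.9), so its rise was not particular to the SMARCA4 null. In the SMARCA4 null, among 38 cell-cycle genes 8 fell and 1 rose in the authors' deposited table (9 and 1 adjusted over the list alone). CDK6 stood at -1.15 and PCNA at -0.53 on the log2 scale. Of 36 HOX genes, 5 fell and 2 rose in the authors' deposited table (6 and 3 adjusted over the list alone), and HOXA2, HOXA5 and HOXA10 had log2 changes of -1.54, -1.27 and -1.16.

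By the authors' deposited table, a total of 2322 genes passed an FDR of 0.05 in the SMARCA4 null, 1444 higher and 878 lower. At least a 2-fold change was found for 926 of them in the authors' deposited table.

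In the double null, genes without wildtype reads rose, among them VIP, C6orf15, MYOC, MUM1L1 and DSG4, which also rose in the SMARCB1 null. Over 227 recovered genes without wildtype reads and with at least 20 reads in the double-null pair, the deeper library held a median of 99.7% of the depth-corrected reads. VIP was at least 656-fold higher (FDR 0.0136 in the authors' deposited table). C6orf15 had 380 and 122 depth-corrected reads in the 2 double-null libraries and MYOC, a secreted glycoprotein gene of the eye, had 181 and 227, with none in wildtype, so that they were at least 159-fold and at least 129-fold higher. MUM1L1, DSG4, the calcium-binding gene CALB2, the cadherin CDH19 and FIBCD1 were at least 104-fold, 64.9-fold, 117-fold, 101-fold and 68.5-fold higher. C8orf4, with 113 and 94.7 depth-corrected reads in the double null and none in wildtype, was at least 65.8-fold higher. For 3 further genes the rise lay mostly in the deeper library. WBSCR17 had 657 and 15.6 depth-corrected reads, ZBED9 had 292 and 9.37 and WSCD2 had 285 and 8.33, and WBSCR17 was not called with edgeR on recovered reads (adjusted p = 0.142). Among recovered genes, 427 exceeded every other library over 4 times in the deeper double-null library alone, and 25 of the 549 recovered genes called higher in the authors' deposited table had over 90% of the pair's depth-corrected reads in a single library.

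The gene for the cytoskeletal protein ermin, ERMN, had a ratio of 0.00351 (FDR 1.88e-113) and HNMT, which inactivates histamine, of 0.00673 (FDR 0.00016) in the authors' deposited table. The retinoic acid synthesis gene ALDH1A2 had a ratio of 0.00141 (FDR 0.0113) in the authors' deposited table, and its FDR was 0.288 in the shorter of the 2 tables. TRIM38, the germ cell gene DAZL and HPGD had ratios of 0.00694, 0.0123 and 0.0123 in the authors' deposited table (FDR 0.00994, 0.0354 and 3.82e-16). The fibrillin gene FBN2 had a ratio of 0.0157 (FDR 1.85e-12), MICALCL of 0.0131 and MYO3B of 0.0145 in the authors' deposited table. UNQ6494 had no reads in the double null and was at least 89.6-fold lower, and GADL1 and MS4A2 went from implied levels of 157 and 1314 to 0.737 and 1.56 depth-corrected reads per library.

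Genes of the cell cycle were called lower in the double null more often than higher. Of 38 cell-cycle genes, 15 fell and 2 rose in the authors' deposited table (16 and 2 adjusted over the list alone), with CDK6 at -1.90, CCND2 at -1.28 and CCND1 up at 2.58 on the log2 scale. Of 39 ribosomal protein genes, 17 fell in the authors' deposited table (23 adjusted over the list alone) by small amounts, RPLP1 by -0.45 and RPS6 by -0.32 on the log2 scale, and 22 were not called. The list's median of -0.18 stood at percentile 10 of random lists, whose median was -0.14, so that as a group it was not set apart from genes of like abundance. Of 21 immediate-early genes 9 rose in the authors' deposited table (10 adjusted over the list alone, with 1 lower), DUSP6 by 4.08 and EGR3 by 3.23 on the log2 scale. HOX genes rose for 9 and fell for 4 of 36 in the authors' deposited table (12 and 4 adjusted over the list alone), HOXB8 by 4.77 on the log2 scale. Of 14 hedgehog pathway genes 4 rose and 4 fell in the authors' deposited table (5 and 4 adjusted over the list alone), the ligand SHH by 4.61 and GLI3 by -2.86 on the log2 scale. Of 39 neuronal genes, 8 rose and 4 fell in the authors' deposited table (8 and 4 adjusted over the list alone), with log2 changes of 9.34 for SCN2A and 9.32 for NEFL. The median of that list was 4.37 on the log2 scale, and 27 of its members were not called in the authors' deposited table. Reads per library were recovered, with at least 20 in the double-null pair, for 1 of the 39, which had 99.96% of its depth-corrected reads in the deeper library, and how the other members were split is not known here. The secretory granule gene CHGA, outside that list and named after its values were seen, had 6672 reads in the deeper library and 14 in the shallower. IGF2 had a ratio of 491 (FDR 1.01e-27) in the authors' deposited table.

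The double null had 3516 genes past an FDR of 0.05 in the authors' deposited table, 2350 higher and 1166 lower, of which 1655 changed at least 2-fold. The median log2 change of all genes was 0.17 in the double null, against 0.06 and 0.03 in the SMARCB1 and SMARCA4 nulls, in the authors' deposited table.

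**Figure D2:**
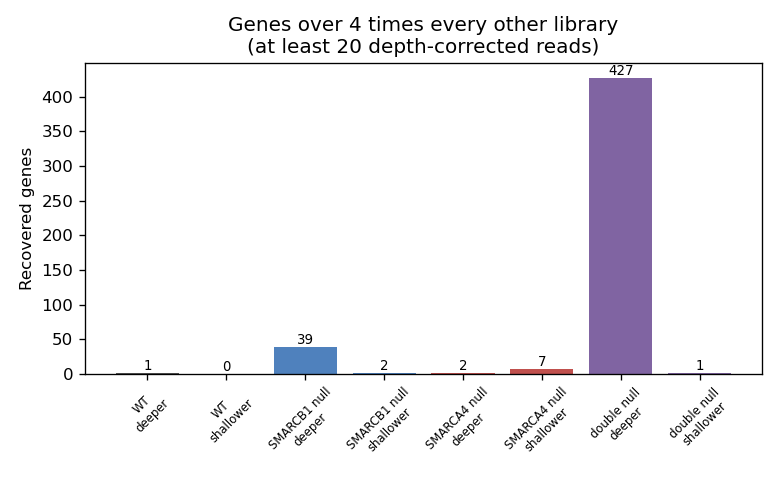
Number of recovered genes in each library whose depth-corrected reads were at least 20 and over 4 times those of every other library. The deeper double-null library held 427 such genes and the deeper SMARCB1-null library 39, and each of the others between 0 and 7.

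Calls overlapped between the nulls. The SMARCB1 and SMARCA4 nulls shared 656 higher and 466 lower genes in the authors' deposited table, where independent lists would share 113 and 50.5, and 131 genes were called in opposite directions. The double null shared 1212 higher and 758 lower genes with the SMARCB1 null (185 and 67.1 for independent lists) and 861 higher and 485 lower with the SMARCA4 null (174 and 52.4) in the authors' deposited table. All 3 comparisons called 606 genes higher and 376 lower in the authors' deposited table. Every comparison used the same wildtype libraries. The double null also shared a guide with 1 sample of each single null. Effects of a shared guide and of the loss cannot be told apart in these overlaps. On 2369 recovered genes the covariance of log2 changes was 2.38 for the double and SMARCB1 nulls, 1.13 for the 2 single nulls and 1.07 for the double and SMARCA4 nulls, against 0.272, 0.279 and 0.27 in simulations of unchanged groups with these controls. The correlations across genes, which are not independent replicates, were 0.751, 0.485 and 0.417, with 0.496, 0.506 and 0.504 simulated. Calls shared among these genes numbered 182 higher and 86 lower, 93 and 59, and 158 and 48 for these pairs, where independent lists would share 45.7 and 7.40, 21.5 and 6, and 49.9 and 5.52. The simulations shared 0.3, 0.2 and 0.15, a weak comparison because unchanged groups give almost no calls. They also lack transcripts confined to single libraries, which the deeper SMARCB1-null and double-null libraries held. As examples chosen after their values were seen, HBB had 134 and 90 reads in these and 0 in both shallower ones, and COL4A2 77 and 1735 against 3 and 5. Such genes could add to the covariance and correlation of the double and SMARCB1 nulls, which were not computed without these libraries. With 1 wildtype library for each of the 2 nulls the correlations were 0.684 and 0.691, 0.393 and 0.445, and 0.338 and 0.391 in the 2 assignments. The correlation exceeded its simulated value only for the double and SMARCB1 nulls. In the 2 assignments no wildtype library was shared between the nulls of a pair, so noise of a shared library does not make up these correlations. Shared calls and covariances were not computed that way, so part of their excess may still come from the shared controls.

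Direct differences between the single nulls were tested on the recovered reads with edgeR, an alternative chosen after seeing the data. TNFAIP6, a secreted hyaluronan-binding protein gene, had 2093 and 1976 depth-corrected reads in the SMARCB1 null and none in the SMARCA4 null (edgeR adjusted p = 0.00355). The enamel protein gene AMBN had 536 and 719 against none (edgeR adjusted p = 1.33e-06), and NDST4, of heparan sulphate synthesis, had 79.7 and 218 against 0 and 1.1 (edgeR adjusted p = 0.00894). In the other direction TRIML2 had 364 and 861 depth-corrected reads in the SMARCA4 null and none in the SMARCB1 null (edgeR adjusted p = 0.00657). EMP1 was lower in the SMARCB1 null by a log2 difference of -4.52 ± 0.70 (SE, edgeR adjusted p = 0.0272), and EVX1, a homeobox gene, by -4.55 ± 0.53 (edgeR adjusted p = 0.000928). In all 277 of 2369 genes differed by edgeR's quasi-likelihood test, 110 higher and 167 lower in the SMARCB1 null, and the count was 115 without the shallower SMARCA4-null library, or 16 with the low-count filter recomputed for that fit. The AMBN call was kept in all 26 alternative fits, whereas NDST4 and TRIML2 lost theirs with voom, TRIML2 and EMP1 with only 4 libraries, EMP1 without either wildtype or either SMARCA4-null library, and all of these but AMBN in some fits with the filter recomputed.

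The double null differed from the SMARCB1 null in SHH, a developmental ligand, at 228 and 241 depth-corrected reads against 3.37 and 12.8 (log2 difference 4.85 ± 0.55, edgeR adjusted p = 0.00219). Later passage and loss of SMARCA4 cannot be told apart in this comparison. SLC38A4 and DOCK10 were higher by 3.92 ± 0.52 and 4.09 ± 0.52 on the log2 scale (edgeR adjusted p = 0.00232 and 0.00219). AMBN and SLC25A48 were lower in the double null by -2.52 ± 0.24 and -3.26 ± 0.34 on the log2 scale (edgeR adjusted p = 0.00126 for both). By edgeR, 100 genes differed, 86 higher and 14 lower, and 52 with TMM scaling, 35 higher and 17 lower. Without the deeper SMARCB1-null library the count was 25, and without the shallower double-null library 372. With the filter recomputed these became 0 by edgeR, where 251 genes had an unadjusted p under 0.05, and 725, and on all 8 libraries DESeq2 with the authors' scaling, DESeq2 with its own size factors and voom called 217, 126 and 68. The calls of these 5 genes were lost in 6 of the 8 fits without a library when the filter was recomputed, and that of SHH also with only 4 libraries.

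Against the SMARCA4 null, the double null had more of the cartilage link protein gene HAPLN1, at 973 and 550 depth-corrected reads against none (edgeR adjusted p = 0.0127). It also had more of NDST4, at 871 and 711 against 0 and 1.1 (edgeR adjusted p = 0.00385). Later passage and loss of SMARCB1 cannot be told apart here. SLFN12 was lower by -4.06 ± 0.44 and the steroid dehydrogenase HSD17B3 by -4.27 ± 0.51 on the log2 scale, with 115 and 125 reads of SLFN12 in the SMARCA4 null against 6.89 and 7.29 (edgeR adjusted p = 0.00041 and 0.000696 for SLFN12 and HSD17B3). EdgeR called 343 genes, 255 higher and 88 lower, and with TMM scaling 288, 157 higher and 131 lower. The count was 105 without the shallower SMARCA4-null library, or 23 with the filter recomputed, and HAPLN1 lost its call without either SMARCA4-null library and, as did NDST4, with voom.

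Departure of the double null from the sum of the single-null changes on the log2 scale was tested in the same fit. The sum therefore stands for multiplied folds and not for added reads. The later passages of the double null enter this departure and cannot be told apart from it. HES3, a transcriptional repressor, had about 1 depth-corrected read in each wildtype library (0.964 and 1.15), 152 and 120 in the SMARCB1 null, 23.9 and 26.5 in the SMARCA4 null and 42.9 and 74.9 in the double null, below the sum (edgeR adjusted p = 0.00138). SLFN12, with 3.86 and 4.62 depth-corrected reads in wildtype, lay below the sum by -5.47 ± 0.66 on the log2 scale (edgeR adjusted p = 0.00162). ZNF385D lay above it (edgeR adjusted p = 0.0094), with 443 and 276 depth-corrected reads in wildtype, 664 and 846 in the SMARCB1 null, 0 and 1.1 in the SMARCA4 null and 276 and 182 in the double null. HES3, SLFN12 and ZNF385D each had a group near the floor, so the sizes of their departures rest on few reads. The number of genes departing from the sum was 120, 70 above and 50 below the sum, and 111 with TMM scaling, 55 above and 56 below. Without the deeper wildtype library it was 17, or 1 with the filter recomputed, and ZNF385D lost its call there and, as did HES3, with voom.

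**Figure D3:**
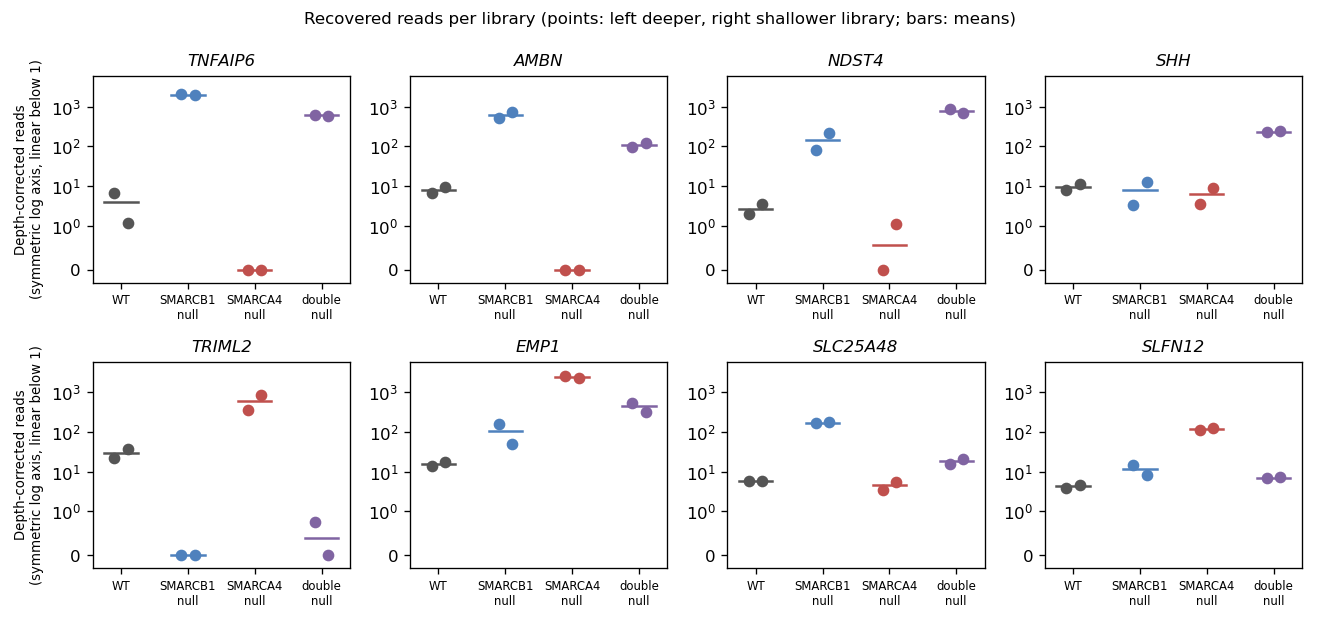
Depth-corrected reads recovered for 8 genes in each library, on a symmetric log axis that is linear below 1, with points for the deeper (left) and shallower (right) library and bars for the mean of 2. TNFAIP6 and AMBN were highest in the SMARCB1 null and without reads in the SMARCA4 null, and SHH was high in the double null at 228 and 241.

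The shorter of the 2 tables held genes that each had a SMARCB1-null FDR under 0.001, at least a 2-fold change and over 1000 total reads by its own columns. This shorter one of the authors' deposited tables listed 269 genes as higher and 140 as lower in the SMARCB1 null. By the same one of the authors' deposited tables, of the 269 genes 178 were also called higher and 9 lower in the SMARCA4 null and 250 higher in the double null, and of the 140 lower genes 70 were called lower and 11 higher in the SMARCA4 null and 121 lower in the double null. The full one of the authors' deposited tables called fewer of the listed genes, both directions together, 325 in the SMARCB1, 185 in the SMARCA4 and 319 in the double null, against 268 and 371 for the last 2 in the shorter. These genes were chosen on the same samples, so their direction is not independent evidence. The same rule applied to the full table took 429 genes, of which 252 were in the shorter table and 177 were not, by the authors' deposited table.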

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

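All tests of explanations in this part were chosen after the result was seen, as was the recovery of reads on which the counts rest.

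Changes differed between the nulls. By edgeR on recovered reads, 277 of 2369 genes differed between the SMARCB1 and SMARCA4 nulls, and 120 departed in the double null from the sum of the single-null log2 changes. These counts were 115 without the shallower SMARCA4-null library and 17 without the deeper wildtype library, and 16 and 1 there with the low-count filter recomputed. Genes far higher in a single library than in any other were also found. The deeper double-null library held 427 recovered genes over 4 times every other library and the deeper SMARCB1-null library 39, and 235 and 13 had at least 20 reads there and 3 or fewer in each other library.

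The 427 were not tested for enrichment, and examples chosen after their values were seen were the neuronal or secretory genes CHGA, with 6672 reads in the deeper double-null library and 14 in the shallower, and SLC17A6, with 3563 and 1, and the imprinted genes NDN, with 2470 and 2, and MAGEL2, with 831 and 1. Over 227 genes without wildtype reads and with at least 20 reads in the double-null pair, the median had 99.7% of the pair's depth-corrected reads in the deeper library. The median ratio between the libraries was 36.1 after depth correction, with 0.5 reads added to each because many had none in the shallower. For these genes as a set, the first value argues against loss of both genes shared by both libraries, and the second against depth. The deeper library alone could bring a gene into this set, so the values do not bear on genes raised in both libraries. RNA from other cells and a change of state of 1 culture both predict a rise of the neuronal list, which had a median log2 change of 4.37 with 24 of 39 members at ratios over 4 in the authors' deposited table, 1 of them recovered with at least 20 reads. Blood and leukocyte genes, named after their values were seen, lay in the same library, with 90 reads of HBB against 0 in the shallower, 136 against 2 of GNLY, 341 against 2 of HLA-DRA, 117 against 2 of S100A9 and 101 against 0 of CD52, while of 5 recovered members of the hematopoietic list with at least 20 reads 2 had over 90% there. The blood genes would be brought by RNA from a mixed source, but were not tested as a prediction, and the 2 explanations cannot be told apart by these values because the genes had been seen before and no library is tied to a passage.

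Skeletal muscle transcripts stood out in the deeper SMARCB1-null library, with 1237 reads of TNNC2 against 1 in the shallower, 1188 against 3 of MYLPF and 82 against 2 of MYOG, and so did the blood gene HBB, at 134 against 0. In the deeper double-null library PVALB had 63 reads against 2, TNNC2 52 against 6, MYLPF 32 against 9 and HBB 90 against 0. The 2 wildtype libraries held 8 and 30 reads of TNNC2 and of MYLPF, but 0 and 4 of PVALB and 0 and 3 of HBB. The double-null ratios were 1.09 for TNNC2, 0.80 for MYLPF and 10.8 for PVALB in the authors' deposited table, so TNNC2 and MYLPF stood near wildtype there. Loss of SMARCB1 shared by both libraries is argued against for the 7 recovered markers, though listed after several had been seen, by a median of 99.9% of the pair's depth-corrected reads in the deeper library, and the other listed markers have no split by library here. RNA from skeletal muscle or myogenic cells may be a source and stays open, since 17 of 22 markers had ratios over 10 in the authors' deposited table, among them the abundant ACTA1 at 99.2 and CKM at 98.3, with 1 of the 22, NEB, called. Over all 35 genes without wildtype reads that median was 69.3%, and a change of state of the culture was not tested. The 2 SMARCB1-null samples had different guides, so a difference between guides cannot be told apart from these explanations either.

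The p-values of the 2 deposited tables differed for the same genes. In the shorter of the authors' deposited tables, the SMARCB1-null p-value was lower than in the full table for 287 genes. Different reads are argued against by equal total reads in 100% of its genes in the authors' deposited tables, and different group means by SMARCB1-null ratios within 5% for 99.5%. Another model or set of tests stays open, and no biological explanation was tested.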

How the results depend on the processing

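The stricter FDR, the fold limits on the authors' calls, the minimum level of 1 read and the rule of the shorter table were planned, and all other alternatives, among them every one on recovered reads, were chosen after seeing the data. No paired analysis was possible because the recovered libraries carry no letter, passage or guide, and for the same reason the passage covariate was not run. Camera and fry were not run, as the full table has no values per library. The recovered tests called 4% of simulated 2-fold rises, and how far depth or group size set this was not tested.

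Shared ratios fixed named genes' direction in the second table (15 results) and edgeR (18). None of 62 named edgeR calls reversed in up to 26 alternative fits, as naming by separated libraries favoured. But 58 were lost in at least 1, 32 with voom and 44 without either wildtype library and the filter recomputed. Of named calls and targets, 29 lost their call at an FDR of 0.01, 4 with edgeR on recovered reads and 1 in the second table, and 52, 14 and 14 stayed on their side of the threshold. Requiring a 2-fold change left 1146, 926 and 1655 calls for the SMARCB1, SMARCA4 and double nulls, and a 1.5-fold change left 1673 and 1425 for the single nulls, by construction. The shared calls numbered 418 between the single nulls and 826 and 498 between the double and the SMARCB1 and SMARCA4 nulls at 2-fold, and 740 between the single nulls at an FDR of 0.01. The rule of the shorter table gave 429 genes on the full table. Of 117 pairs of list and comparison, 59 medians lay outside the central 95% of matched random lists and 56 of unmatched ones. For lists of independent genes 5.85 would lie there. Members of a list can vary together and the comparisons share the wildtype libraries, so these counts are a description and not a test.

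On recovered reads the counts of edgeR moved more, and except for the number of genes or libraries entering a fit the cause was not tested. Without a filter on low counts (4360 genes) the calls were 217, 166 and 401 for the SMARCB1, SMARCA4 and double nulls, 125 between the single nulls, 21 and 130 for the double null against the SMARCB1 and SMARCA4 nulls and 53 for the departure from the sum. With voom these were 207 and 222 for the single nulls, 145 between them, 228 for the double against the SMARCA4 null and 53 for the departure. With only the 4 libraries of a comparison they were 534 and 638 for the single nulls, and 15 and 167 for the double null against the SMARCB1 and SMARCA4 nulls. The double null against the SMARCB1 null gave 163 with at least 50 reads in 2 libraries, 52 with TMM and 217 with DESeq2 on the authors' scaling. Without both deeper libraries in doubt, the SMARCA4 null gave 628, or 643 with the filter recomputed, which gave 559 and 588 for the single nulls and 23 for the double against the SMARCB1 null with only 4 libraries.

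Leaving out each library in turn, with the lone sample of a group assumed to vary like the others, gave 138 to 515 calls for the SMARCB1 null, 86 to 503 for the SMARCA4 null, 235 to 746 for the double null, 115 to 444 between the single nulls, 25 to 372 and 105 to 565 for the double null against the SMARCB1 and SMARCA4 nulls, and 17 to 323 for the departure. Without the deeper or the shallower wildtype library the calls were 138 and 153 for the SMARCB1 null, 110 and 86 for the SMARCA4 null, 260 and 235 for the double null, 41 and 41 and 222 and 216 for the double null against the SMARCB1 and SMARCA4 nulls, and 17 and 34 for the departure. Without the deeper SMARCB1-null library they were 218 for that null, 149 between the single nulls, 25 for the double against the SMARCB1 null and 77 for the departure, and without the shallower 151 between the single nulls and 38 for the double against the SMARCB1 null. Without the deeper or shallower SMARCA4-null library they were 184 and 151 for that null, 142 and 115 between the single nulls, 52 and 53 and 147 and 105 for the double null against the SMARCB1 and SMARCA4 nulls, and 49 and 68 for the departure. Without the deeper double-null library the single nulls differed in 444 genes, and without the shallower in 419, with 372 and 565 for the double null against the SMARCB1 and SMARCA4 nulls and 323 for the departure.

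With the filter recomputed (2604 to 3216 genes), which was seen first, these ranges were, in the same order, 24 to 494, 1 to 485, 74 to 1109, 16 to 427, 0 to 725, 20 to 924 and 0 to 416. The lows of 24, 1 and 74 came without a wildtype library. By edgeR 7 of 56 counts were 0. For the double against the SMARCB1 null this was without either SMARCB1-null library (251 and 395 genes at an unadjusted p under 0.05) or either SMARCA4-null library (420 and 425), and for the departure without the deeper SMARCB1-null (343) or either SMARCA4-null library (335 and 341). On all 8 libraries DESeq2 with the authors' and its own scaling and voom called 217, 126 and 68 genes for the first and 175, 151 and 53 for the second, and were not run with a library left out.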

Other observations

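Of the tests in this part, that of chromosome copies was chosen after the result was seen, and that of nearly unexpressed genes before.

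Some mesenchymal genes rose in each null. The smooth muscle actin gene ACTA2 had log2 changes of 3.82 in the SMARCB1 null and 2.28 in the double null, and calponin CNN1 of 1.87, 2.83 and 3.86 in the SMARCB1, SMARCA4 and double nulls, in the authors' deposited table. Of 22 mesenchymal genes 6, 5 and 7 rose and 2, 1 and 2 fell in the authors' deposited table (9, 5 and 10 rose and 2, 1 and 2 fell adjusted over the list alone). Among 10 markers of fibroblasts, included because cultured lines can hold feeder cells, 2, 2 and 4 rose in the authors' deposited table (6, 3 and 6 adjusted over the list alone), with PDGFRA at 2.86, 7.05 and 5.49 on the log2 scale. Of 40 extracellular matrix genes 4, 3 and 7 rose and 6, 3 and 6 fell in the authors' deposited table (4, 3 and 8 rose and 7, 3 and 6 fell adjusted over the list alone). Of those with recovered reads and at least 20 in the pair, 5 of 6 had over 90% of the depth-corrected reads in the deeper SMARCB1-null library and 6 of 8 in the deeper double-null library, with 747 reads of TNC against 1 and 1735 of COL4A2 against 5 in the double null and 176 of BGN against 0 in the SMARCB1 null. Of 4 and 5 such mesenchymal genes 2 and 1 had over 90% there, PRRX1 with 82 reads against 1 in the double null. For fibroblast markers the median share was 78.7% and 69.6%, over 2 genes each. Of 17 proteoglycan genes, 4 fell in the SMARCB1 null, 3 rose in the SMARCA4 null and 4 rose and 4 fell in the double null in the authors' deposited table (5, 3, 5 and 4 adjusted over the list alone). The proteoglycan genes VCAN, SDC2 and GPC3 had log2 changes of -3.67, -3.41 and -1.67 in the SMARCB1 null in the authors' deposited table, whereas SDC2 and GPC3 rose by 2.15 and 1.67 in the SMARCA4 null and had log2 changes of -2.08 and -3.57 in the double null.

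Nuclear genes of oxidative phosphorylation rose by small amounts in the SMARCB1 null, 6 of 37 in the authors' deposited table (9 adjusted over the list alone), with UQCRC2 up by 0.47 on the log2 scale. In the SMARCA4 and double nulls 3 and 2 of the 37 rose and 0 and 1 fell in the authors' deposited table (3 and 2 rose and 0 fell adjusted over the list alone). The list's median log2 change was 0.23, 0.13 and 0.20 in the SMARCB1, SMARCA4 and double nulls. Of 29 interferon response genes 5, 4 and 5 rose and 3, 1 and 3 fell in the SMARCB1, SMARCA4 and double nulls in the authors' deposited table (6, 4 and 5 rose and 3, 1 and 3 fell adjusted over the list alone). The interferon-induced IFITM1 had log2 changes of -3.93, -4.97 and -3.07 in the SMARCB1, SMARCA4 and double nulls in the authors' deposited table, whereas MX1 rose by 2.64, 1.96 and 2.95. The developmental regulator OTX2, named after its values were seen, had ratios of 0.0905, 0.339 and 0.221 in the authors' deposited table (FDR 3.89e-39, 6.06e-24 and 9.53e-34).

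A gain or loss of a whole chromosome in a null line was a further hypothesis. Over the 23 chromosomes and 3 comparisons, the largest departure of a chromosome's median from that of all genes was 0.10 on the log2 scale in the authors' deposited table, which argues against a gain or loss carried by all cells of a line.

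Nearly unexpressed genes rose in the double null, and reads of its deeper library may account for this. Over 1132 recovered genes with up to 30 reads, the median log2 change with 0.5 reads added was 1.04 with both double-null libraries, 1.19 with the deeper alone and 0 with the shallower alone. Of these genes, 144 had no reads in the shallower double-null library or in wildtype.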
